A study of Mus musculus with 4 samples.

How the data were processed

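Total RNA came from epithelial cells shaken off mouse colon with a chelating buffer, per the labels' protocols. The libraries are inputs of a methylated RNA immunoprecipitation experiment, in which an antibody enriches RNA carrying N6-methyladenosine (m6A) and the input is the RNA that has not been enriched. There are 4 input libraries, 2 labelled wild type (WT) and 2 labelled Ythdf1 knockout (KO). Immunoprecipitated libraries were not analysed here. The labels do not say whether the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

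Per the submitters' processing notes, the tools of the series were CASAVA 1.8, Bowtie2 2.2.5, SAMtools 1.3.1, MACS2 2.1.0, HOMER 4.10 and deepTools 3.3.0, and the genome build was mm10. The notes give these names with no role or order. The program that counted reads and the program behind the authors' comparison are not given in the sources used here, nor is it stated whether counting used strand. Reads of overlapping genes, of antisense pairs and of near-identical copies such as ribosomal protein pseudogenes may therefore not be told apart.

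The table lists 87526 RefSeq transcripts of 25797 genes, on average 3.39 transcripts per gene and at most 55. The deposited expression signal of each transcript is a normalised read count: in each library, 100% of the values were whole multiples, within 0.001, of the lowest value above 0. These values are therefore read counts divided by a size factor per library. A value of 1.13 stood for 1 read in WT 1, 1.01 in WT 2, 0.969 in the library labelled Ythdf1 KO 1 and 0.827 in that labelled Ythdf1 KO 2. Isoforms of a gene each count the reads they share. The authors listed no transcript with a mean under 11.6 over the 4 libraries and no mitochondrially encoded transcript, as read from the values, so absent transcripts have no level here. Per the file headers, the authors also gave a log2 fold change, a p-value and a q-value per transcript. The log2 fold change follows the KO mean over the WT mean, and the deposited q-value is the Benjamini-Hochberg adjustment of the p-value over all listed transcripts, to within 2.61e-15.

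Taking the most abundant transcript of each gene, the recovered reads came to 21686165 in WT 1, 24576450 in WT 2, 25936859 in Ythdf1 KO 1 and 30951376 in Ythdf1 KO 2. Over all transcripts, with shared reads counted again for each isoform, they came to 85376141, 96073467, 101883440 and 120461859 in the same order. Spearman's correlation between libraries over all genes lay between 0.831 and 0.85, and no pair of libraries held identical values above 0. The libraries did not group by label. The highest value joined WT 2 and Ythdf1 KO 2, above 0.841 between the WT libraries and 0.847 between those labelled Ythdf1 KO. On genes with a mean of at least 500, Pearson's correlation of log2 values was 0.936 within WT and 0.91 within the other group. Ythdf1 KO 1 stood at 0.928 and 0.93 to WT 1 and WT 2 there.

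Transcript values were summed per gene. Genes with a value of at least 1 in at least 2 libraries were kept, which left 23252, and log2(value + 1) was fitted with limma-trend 3.58.1 (robust) in R 4.3.3, with genotype label as the only term. The values are size-factor-normalised counts, a unit that the plan had not listed by name. They were handled as normalised values, so no count test is the main result. Calls needed a Benjamini-Hochberg adjusted p under 0.05. The log2 differences of limma-trend are on the log2(value + 1) scale, which understates the change of genes with low values. Ratios are of group means without the added 1, and the authors', edgeR and DESeq2 fold changes are on their own scales. Summing isoforms gives more weight to reads that several isoforms share, so the most abundant transcript of each gene was an alternative. Where both libraries of a group were at 0, the fold was computed on the most abundant transcript against 3 reads per library, averaged over the group, and is given as a lower bound; such floors cover counting error only.

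Gene lists covered m6A machinery, epithelial cell types, junctions, defence, stress, metabolism, translation, the clock, Hox genes of the distal hindgut, sex-linked genes and markers of other cells or tissue. There were 31 lists with 658 entries, of which 620 were matched by symbol, 2 through RefSeq gene identifiers, and 36 were not listed in the table. Lists with at least 3 tested genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 30 lists that qualified. An estimated correlation and fry were run beside it. With an estimated correlation the test rests on 2 residual degrees of freedom here and has little power. Even lists with a negative estimated correlation, such as the sex-linked list (-0.134), got a larger p there. A call lost in that test therefore does not decide against a list. The preset correlation lies far below the estimates for both called lists, 0.375 for ribosomal proteins and 0.196 for interferon response. Where genes vary together that much, the preset p is too small, so a call at the preset correlation is uncertain too. Each list's median was also set against 10000 random lists matched on mean level, as a description of these libraries.

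The main test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. By the rule, Ythdf1 and the m6A machinery are given. Of genes past the threshold, the 12 largest changes in each direction would be named, and where none pass, the 5 with the smallest p in each direction. Those need a mean of at least 5 in the higher group, and symbols of predicted genes, immunoglobulin or T cell receptor segments and pseudogenes are left out. Up to 4 members of a called list and up to 2 of another described list are named, by smallest p. Named genes of the authors' deposited table were chosen after their values were seen: up to 12 of the smallest q in each direction among genes with a mean of at least 500 in their most abundant transcript, with the same symbols and those starting with LOC left out, and members of the fixed lists that the authors called.

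Alternatives fixed beforehand were quantile normalisation, limma without a trend, limma without robust fitting, other filters, another pseudocount, the replicate number as a block, the most abundant transcript, single transcripts, other thresholds, leaving out ribosomal RNA and the 20 most abundant genes, leaving out each library, and the authors' own comparison. Alternatives chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the most abundant transcript of genes with a mean of at least 500, an estimated correlation in each of the other fits, and the authors' values for the most abundant transcript of each gene. The direction of a list in the alternatives was read from its median, a choice also made after seeing the data. Figures were drawn with matplotlib 3.10.9.

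The fits were tested on simulated counts of the most abundant transcript of the 25797 genes, not of summed transcripts. In them 200 genes were changed, all with a mean of at least 100, so any other call counts as unchanged. At the spread estimated from the 4 libraries, limma-trend recovered 3 of 100 genes changed by 1 on the log2 scale and 45 of 100 changed by 2, and called 0 unchanged genes. edgeR recovered 3 and 45 of 100 and called 12 unchanged genes. DESeq2 recovered 16 and 56 of 100, and 348 of its 420 calls, 82.9%, were unchanged genes. That share depends on how many genes were changed and is not an estimate for the data. At a small spread (dispersion 0.01), limma-trend recovered 100 of 100 at either size. DESeq2 there recovered 90 and 100 of 100, and 3 of its 193 calls, 1.55%, were unchanged genes. Of 2 lists of 30 genes simulated in the same manner, camera called the shifted one (median log2 difference 0.98) and not the unchanged one (0.012).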

Results

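RNA was sequenced from 4 input libraries of mouse colon epithelial cells, 2 labelled WT and 2 labelled Ythdf1 KO. Ythdf1 encodes a cytoplasmic reader protein that binds m6A, the commonest internal base modification of mRNA. The comparison of the labelled groups asks which RNAs differed in level, before any enrichment for m6A, between epithelium labelled WT and epithelium labelled as lacking the gene. The depth behind it was 21686165 to 30951376 recovered reads per library, counted on the most abundant transcript of each gene.

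The gene that the knockout targets was not lower in the libraries labelled Ythdf1 KO. Ythdf1 (gene ID 228994, transcript NM_173761.3, mm10 chromosome 2, 180904377 to 180920936) had normalised read counts of 1088 in WT 1 and 775.4 in WT 2, against 1752 and 1737 in the libraries labelled Ythdf1 KO 1 and 2. The means were 931.5 ± 221 (SD, n = 2) and 1744 ± 10.5 (SD, n = 2), a ratio of 1.87. This level neither bears out the labels nor decides against them, so every direction here follows the labels and not a checked genotype. Which part of the gene was altered is not given in the sources used here, and a level over the whole transcript cannot show whether protein was made. In limma-trend the log2 difference was 0.93 ± 0.37 (SE), with an adjusted p = 0.732. The authors' deposited table gave Ythdf1 a log2 fold change of 0.91 with q = 0.0145, and DESeq2 on the most abundant transcript gave an adjusted p = 0.0138.

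The other cytoplasmic readers of the family and the enzymes of the m6A pathway did not pass the test either. Ythdf3 had means of 8711 ± 1030 (SD, n = 2) in WT and 11690 ± 1200 (SD, n = 2) in the libraries labelled Ythdf1 KO, and Ythdf2 1177 ± 611 and 1626 ± 505 (SD, n = 2 each). The direction of Ythdf2 turned without WT 1. Of the 23 members of the m6A machinery list, 6 lay above both WT libraries in both libraries labelled Ythdf1 KO and 2 lay below, where chance gives a share of 16.7% on each side. Alkbh5, a demethylase of m6A, was among the 6, at 4863 ± 329 and 6773 ± 378 (SD, n = 2 each). Cbll1, a subunit of the methyltransferase complex, was below, at 5849 ± 990 and 3405 ± 1340. The list had a median log2 difference of 0.13, a mean of 0.00074 and a camera adjusted p = 0.405, and its median was 0.03 without WT 2 and 0.05 without Ythdf1 KO 2. The authors' deposited table called 2 of its members, Ythdf1 and Alkbh5, both higher.

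**Figure D1:**
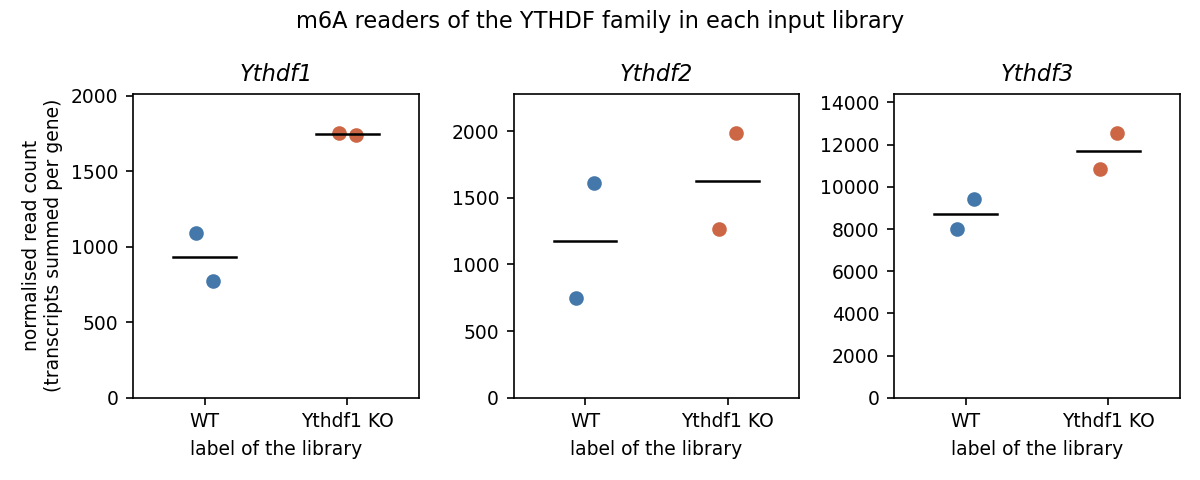
Normalised read count (transcripts summed per gene, linear axes from 0) of Ythdf1, Ythdf2 and Ythdf3 in the libraries labelled WT and Ythdf1 KO; each point is a library and each black line the mean of 2. Both points of Ythdf1 labelled KO, at 1752 and 1737, lie above the WT points at 1088 and 775.4.

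Across all genes, the smallest p values in limma-trend belonged to genes with differences of 1.99 times or more between the labelled groups, none past the threshold. Toward the libraries labelled Ythdf1 KO these were Zfp385b, Adgrg1, an adhesion G protein-coupled receptor, Pacsin3, a membrane-bending protein of endocytosis, Smpd4, a neutral sphingomyelinase, and Kat2a, a histone acetyltransferase. Kat2a had means of 3277 ± 817 and 9440 ± 1320 (SD, n = 2 each), a ratio of 2.88. Adgrg1 had means of 24580 ± 600 and 48880 ± 5640, a ratio of 1.99, and Pacsin3 a ratio of 6.18. Smpd4 and Zfp385b had ratios of 2.39 and 3.56.

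Toward the WT libraries they were Sox5, a transcription factor, Dab1, an adaptor of Reelin signalling, Tnnt3, the troponin T of fast skeletal muscle, Mospd1 and Gstm4, a glutathione transferase. Sox5 had means of 4677 ± 642 in WT and 1154 ± 27.7 in the libraries labelled Ythdf1 KO (SD, n = 2 each), summed over 28 transcripts. Its most abundant transcript stood at 142 and 256.4 in WT against 42.66 and 40.53. On the most abundant transcript Sox5, Dab1 and Tnnt3 had no unadjusted p under 0.05 in limma-trend. Mospd1, Gstm4 and the genes named on the higher side did, so the order by p depends in part on the summing. Gstm4 had means of 1583 ± 19.2 and 178.7 ± 27. Mospd1 and Dab1 had ratios of 0.244 and 0.125 (labelled KO over WT). Tnnt3 stood at 2397 and 2101 in WT and at 0 in both libraries labelled Ythdf1 KO, at least 37.5-fold lower there on its most abundant transcript. That transcript stood at 186 in WT 1 and 16.15 in WT 2, so WT 1 sets the limit, which is 5.99-fold on WT 2 alone.

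In limma-trend 0 of 23252 genes passed an adjusted p of 0.05, the smallest being 0.732. An unadjusted p under 0.05 was found for 1529 genes where chance gives 1163, 450 of them higher and 1079 lower in the libraries labelled Ythdf1 KO. That count fell under chance and its balance turned without WT 1 (607 where chance gives 1056, 402 higher and 205 lower) and without WT 2 (658 where chance gives 1051, 430 and 228), and without a filter it was 1286 where chance gives 1290. Without Ythdf1 KO 1 it was 2001 where chance gives 1100 (373 higher and 1628 lower), and without Ythdf1 KO 2 it was 1880 where chance gives 1101 (250 and 1630). With quantile normalisation it was 1245 where chance gives 1163 (516 higher and 729 lower). edgeR on recovered reads called 0 genes, with 1168 at an unadjusted p under 0.05 on summed reads where chance gives 1123, and 1038 on the most abundant transcript where chance gives 1115. limma-trend on single transcripts called 0, with 3649 at an unadjusted p under 0.05 where chance gives 4109. Other tools differed: limma without a trend called 352 genes, DESeq2 657 on summed reads and 1110 on the most abundant transcript, and the authors' deposited table holds q under 0.05 for 3214 transcripts, or 1152 genes by their most abundant transcript. In the simulation of this comparison most DESeq2 calls were unchanged genes, and limma-trend found 45 of 100 genes changed by 2 on the log2 scale, so a smaller change was seldom detectable with these libraries.

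As a group, ribosomal protein genes were called higher in the libraries labelled Ythdf1 KO at camera's preset correlation only. The test with an estimated correlation had little power here. The list's estimated correlation of 0.375 was far above the preset 0.01, however, so the preset p may be too small. The 77 genes had a median log2 difference of 0.20 (camera adjusted p = 0.00503, and adjusted p = 0.875 with an estimated correlation). Of them, 30 lay above both WT libraries in both libraries labelled Ythdf1 KO, against 2 below, where chance gives a share of 16.7% on each side. That share is a loose reference, since lists matched on level had a median of 0.07 and the members vary together (estimated correlation 0.375). Rps10 had means of 6409 ± 376 and 9300 ± 1410 (SD, n = 2 each), Rps9 14170 ± 1250 and 19430 ± 2460, Rplp1 7574 ± 181 and 10120 ± 590, and Rpl31 9794 ± 1420 and 13350 ± 1670. No single member passed over all genes, and 0 passed adjusted over the list alone. The list's call was also lost with fry (adjusted p = 0.868), with quantile normalisation (0.338), without WT 1 (0.383) and without Ythdf1 KO 2 (0.19). Ribosomal protein genes have many processed copies in the genome, so their counts are uncertain.

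Interferon response genes were the other list called, also higher in the libraries labelled Ythdf1 KO and also at the preset correlation only. Its 31 genes had a median log2 difference of 0.24 (camera adjusted p = 0.041, and adjusted p = 0.875 with an estimated correlation), with 10 members above and 2 below both WT libraries. Oasl2, an oligoadenylate synthetase-like protein, had means of 8481 ± 1240 and 15040 ± 1410 (SD, n = 2 each). Isg15, a ubiquitin-like modifier, had 503.1 ± 146 and 1070 ± 131, Ifi44 142.1 ± 44.7 and 476.8 ± 54.5, and Ifit2, an antiviral RNA-binding protein, 571 ± 492 and 1734 ± 99.3. None of the members passed over all genes, and 0 passed adjusted over the list alone. This call too was lost with fry (adjusted p = 0.868), and further with quantile normalisation (0.118), with the replicate block (0.0537), on the most abundant transcript (0.0507; 0.233 for a mean of at least 500), without WT 1 (0.509) and without Ythdf1 KO 1 (0.326).

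Several lists came close to the threshold. Immediate early and heat shock genes had a median of 0.28 (camera adjusted p = 0.053), with 8 of 21 members above both WT libraries and 0 below. Fos, an immediate early transcription factor, had means of 22600 ± 2550 and 30680 ± 923 (SD, n = 2 each), and Atf3, a stress-induced transcription factor, 5554 ± 1560 and 8785 ± 1090. Translation factors had a median of 0.14 (0.053), and among them Eif5a, which carries hypusine, had 22410 ± 783 and 35150 ± 4630. Hox genes of the distal hindgut had a median of 1.07 (0.053) over 6 genes, 4 of them above both WT libraries. Hoxd13 stood at 596.3 and 462.4 in WT and at 721.3 and 1998 in the libraries labelled Ythdf1 KO 1 and 2, so its mean rests largely on the latter. Proliferation genes had a median of 0.34 (0.0695). Rrm2, a subunit of ribonucleotide reductase, had 241 ± 60.9 and 705 ± 251, and Mki67, a marker of cycling cells, 27880 ± 4540 and 38140 ± 4910. These lists depended on single libraries. The Hox list passed without Ythdf1 KO 1 (adjusted p = 0.00129) but had a median of 0.33 without Ythdf1 KO 2 (0.509). Translation factors passed without Ythdf1 KO 1 (0.0268), with medians of 0.07 without Ythdf1 KO 2 (0.323) and 0.08 without WT 1 (0.617). The immediate early list passed without WT 1 (0.0259) but had a median of 0.03 without WT 2 (0.773), and the proliferation median was 0.10 without WT 1 (0.509). The Hox, translation factor and immediate early lists also passed without a filter (adjusted p = 0.0483, 0.0487 and 0.0483) and in edgeR on summed reads (0.047 each). With an estimated correlation none of these passes held (adjusted p = 0.862 without a filter and 0.838 in edgeR), but that test had little power here.

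Epithelial cell-type lists did not pass camera in the main fit. Absorptive colonocyte genes had a median of -0.10 (camera adjusted p = 0.933), with 9 of 24 below both WT libraries and 4 above, and the median was -0.18 without Ythdf1 KO 2 and -0.17 with quantile normalisation. Car1, a carbonic anhydrase of colonocytes, had means of 317400 ± 25700 in WT and 169100 ± 63700 in the libraries labelled Ythdf1 KO (SD, n = 2 each), and Ceacam1, an adhesion molecule, 376000 ± 18400 and 304800 ± 29000. Goblet cell genes had a median of 0.12 (0.27). Creb3l1, a transcription factor of secretory cells, had 8291 ± 84.6 and 11660 ± 1200, and Sytl2, a protein of vesicle transport, 29000 ± 837 and 38100 ± 3880. Stem cell and Wnt target genes had a median of 0.0054 and a mean of -0.56 (0.756), and Sox9, a transcription factor of crypt cells, had 4199 ± 634 and 6981 ± 492. Enteroendocrine genes had a median of -0.38 (0.756). Neurog3, the transcription factor that starts endocrine differentiation, stood at 166.8 and 145.4 in WT and at 0.97 and 0.827, about 1 read, in the libraries labelled Ythdf1 KO. Pax4, another endocrine transcription factor, stood at 590.6 and 201.9 and at 0 in both, at least 40.1-fold lower on its most abundant transcript (18.7-fold on WT 2 alone). Tuft cell genes had a median of -0.13 and a camera direction of up (0.677).

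Junction, defence and stress lists gave values on both sides. Cell junction genes had a median of 0.038 and a mean of -0.11 (camera adjusted p = 0.598), and Cldn2, a pore-forming claudin, had means of 6739 ± 1390 and 12300 ± 189 (SD, n = 2 each). Cldn1, another claudin, went the other way at low values, with 58.61 and 54.52 in WT and 0.97 and 3.309 in the libraries labelled Ythdf1 KO. Antimicrobial defence genes had a median of 0.29 (0.382), passing only without WT 2 (0.0128, and adjusted p = 0.944 with an estimated correlation), NF-kB and cytokine genes a median of 0.033 and a mean of -0.17 (0.698), and MHC class II genes a median of -0.70 (0.433), which was -0.30 without Ythdf1 KO 1 and -0.17 with quantile normalisation. Ciita, the activator of MHC class II genes, had 2165 ± 251 and 1136 ± 62. The unfolded protein response had a median of 0.24 (0.143), with 8 of 22 members above both WT libraries and 1 below (medians of 0.14 without WT 2 and 0.15 without Ythdf1 KO 2). Its sensor kinase Eif2ak3 had 3692 ± 516 and 5948 ± 42.1. The only member called in the authors' deposited table, Dnajb9, was lower in the libraries labelled Ythdf1 KO (fold 0.521, q = 0.023 in that table). Ferroptosis and redox genes had a median of -0.08 with a camera direction of up (0.698), and Acsl4, which activates polyunsaturated fatty acids, had 1006 ± 163 and 3510 ± 1300. For p53 and apoptosis genes the median was 0.10 (0.433).

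Metabolic lists did not pass in this fit. Fatty acid oxidation and ketogenesis genes had a median of -0.025 with a camera direction of up (camera adjusted p = 0.792), cholesterol synthesis genes -0.12 (0.933) and circadian clock genes 0.10 (0.433). Xenobiotic and glutathione enzymes had a median of -0.39 (0.795), which was -0.10 without Ythdf1 KO 2, -0.73 without Ythdf1 KO 1, -0.15 with quantile normalisation and -0.16 in edgeR on summed reads. Among 10000 lists matched on level, the medians of the xenobiotic, absorptive colonocyte and cholesterol lists lay at percentiles 0.08, 0.9 and 3.4 in the limma-trend fit. On the most abundant transcript of genes with a mean of at least 500, the xenobiotic and absorptive colonocyte lists passed, both lower in the libraries labelled Ythdf1 KO (medians of -0.52 and -0.13, adjusted p = 0.0105 and 0.0417). Neither pass held with an estimated correlation (adjusted p = 0.823 for each), a test of little power here. Abcb1a, a drug efflux transporter, had means of 99180 ± 242 and 70360 ± 17800 (SD, n = 2 each). The sex-linked list had a median of 0.51 (0.162), and no mitochondrially encoded gene was listed. The sex-linked list pools Xist with Y-linked genes, so its median does not measure a difference in sex. The Y-linked Eif2s3y stood at 4799 and 3787 in WT and at 6578 and 8179 in the libraries labelled Ythdf1 KO, so Y-linked RNA was counted in all 4 libraries.

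Several lists of markers of other cells had medians below 0 in the libraries labelled Ythdf1 KO. Myeloid genes had a median of -1.15 (camera adjusted p = 0.282), with 0 of 14 above and 2 below both WT libraries. That median was -0.33 without WT 1, -1.97 without WT 2, -0.30 without Ythdf1 KO 1 and -0.14 with quantile normalisation. Lyz2, a macrophage lysozyme, stood at 47.34 and 73.7 in WT and at 0 in both others, at least 22.5-fold lower (17.6-fold on WT 1 alone). Lymphocyte and plasma cell genes had a median of -0.55 (0.933), endothelium and nerve genes -0.53 (0.704), stroma and muscle genes -0.18 (0.933), erythroid genes 0.73 (0.433) and small intestine genes 0.0048 with a camera direction of down (0.991). With quantile normalisation the lymphocyte, endothelium and erythroid medians were -0.06, -0.13 and 2.06, and the stroma and small intestine medians were 0.272 and 0.345. Ptprc, the pan-leukocyte antigen, had means of 3781 ± 2340 and 1497 ± 665 (SD, n = 2 each), and Pdgfra, a receptor of fibroblasts, 1282 ± 137 and 238.1 ± 219. Lists matched on level had a median of -0.56 beside the myeloid list, so low-level genes in general shared the direction. Setting genes at 0 in a group to their bound left every list's median as given. In fry's test for change in either direction, 3 lists passed, the myeloid, enteroendocrine and cell junction lists.

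**Figure D2:**
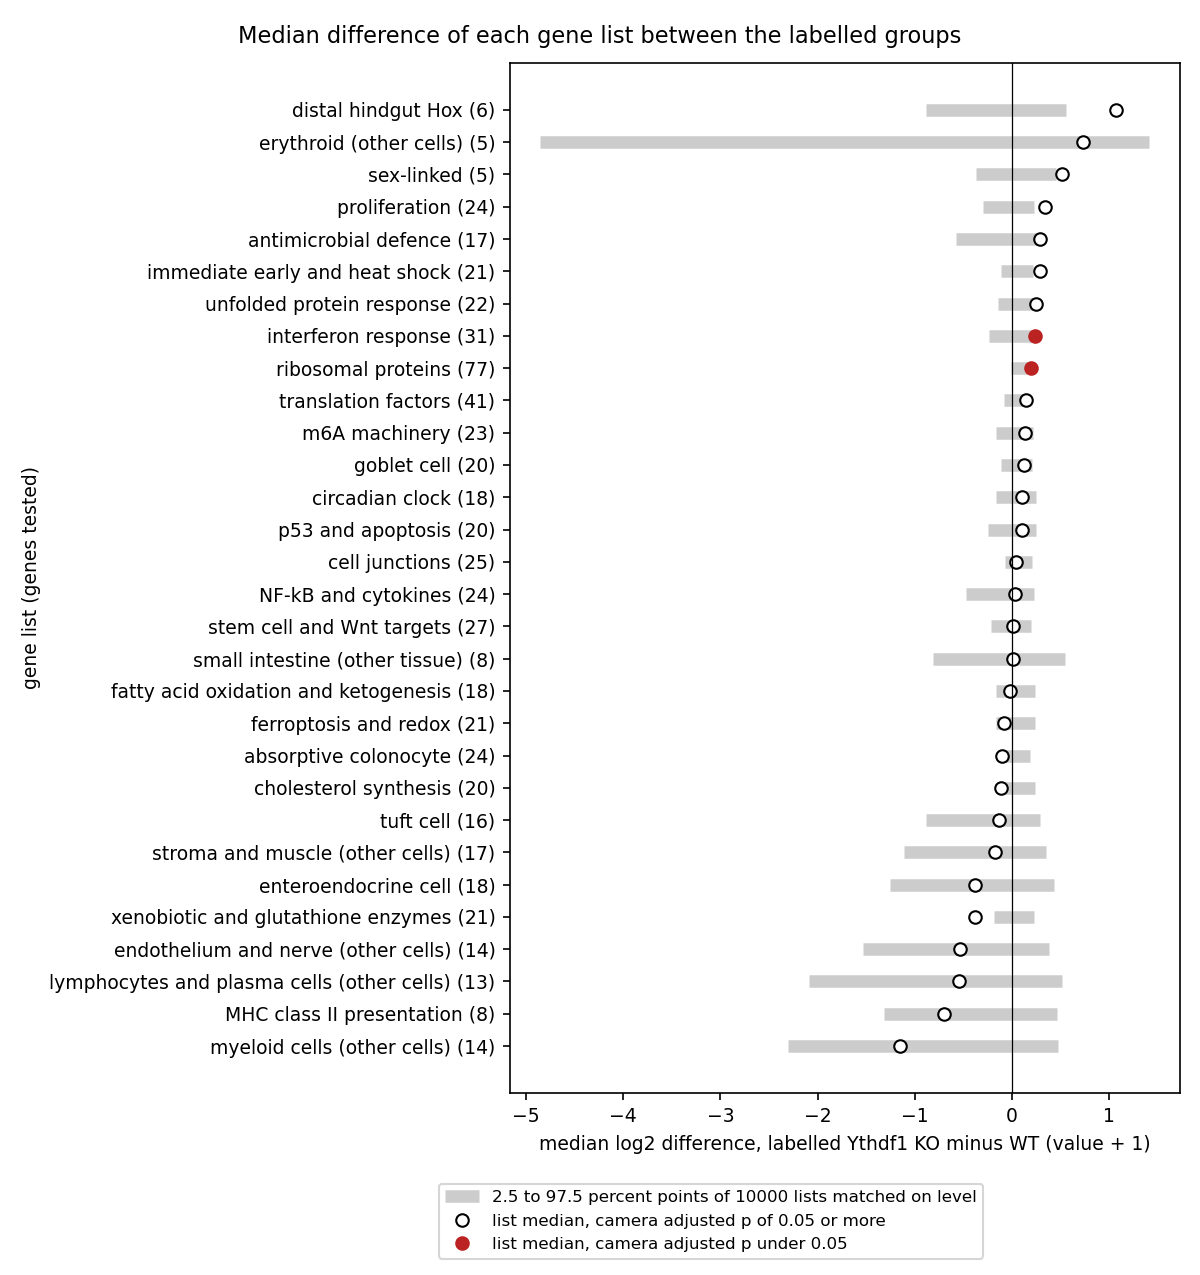
Median log2 difference (horizontal axis, labelled Ythdf1 KO minus WT, on value + 1) of 30 gene lists, one per line with its number of tested genes; grey bars span the central 95% of 10000 lists matched on level, and filled points mark a camera adjusted p under 0.05. The filled points are ribosomal proteins at 0.20 and interferon response at 0.24.

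Among abundant genes, the authors' deposited table leaned toward the libraries labelled Ythdf1 KO. Of 7431 genes with a mean of at least 500 in their most abundant transcript, 230 had q under 0.05 in the authors' deposited table, 168 higher and 62 lower. Its smallest q values on the higher side included Hist1h3c, a histone H3 gene, at 1721 and 1572 in WT and 3330 and 3544 in the libraries labelled Ythdf1 KO (q = 4.15e-07 in the authors' deposited table). Ctse, an aspartic protease, stood at 388.9 and 361.4 against 1094 and 1964, and Ly6e, an interferon-inducible surface protein, at 4186 and 4246 against 6986 and 9174. Timm50, part of the mitochondrial import machinery, had a fold of 2.98 in the authors' deposited table, Cpq, a carboxypeptidase, 2.94, and Nbl1, an antagonist of BMP signalling, 4.99. Kat2a had a fold of 2.71 there, Cldn2 2, Slfn4 1.68, Mptx1, a pentraxin, 1.66, and Hspa8, a constitutive chaperone, 1.52.

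On the lower side of the authors' deposited table, Mal, a protein of apical membrane transport, stood at 1575 and 1740 in WT and 602.1 and 601.4 in the libraries labelled Ythdf1 KO (q = 1.78e-07 in that table). Mrgpra6 was the most abundant of this set, at 73650 and 82540 against 55300 and 44670. These values belong to NR_131899.1, whose RefSeq prefix marks a non-coding RNA. Tbx3, a T-box transcription factor, had a fold of 0.434 in the authors' deposited table, Mpp6 0.357, Paqr8 0.374, Pex16, a peroxisome assembly factor, 0.409, and Fam98a 0.475. Slc39a4, a zinc importer, had 0.617 there, Tsku 0.56, Fbxo18, a DNA helicase, 0.578, Igdcc4 0.633 and Myo9b, a myosin, 0.67. In limma-trend on the same 7431 genes, 0 passed, the smallest adjusted p being 0.453, with 451 at an unadjusted p under 0.05 where chance gives 372. Of these, 313 were higher and 138 lower.

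Genes of low level showed the opposite balance in the authors' deposited table. Of 14991 genes with a mean under 200, that table called 851, 132 higher and 719 lower in the libraries labelled Ythdf1 KO, a lower share of 84.5% against 27% among the abundant genes. Pax4, Neurog3, Ccl25, a chemokine of gut epithelium, and Gzma, a granzyme of lymphocytes, were list members among those lower calls. Of transcripts called in the authors' deposited table, 957 were at 0 in both libraries labelled Ythdf1 KO and 150 at 0 in both WT libraries. At means from 20 to 50, 33.4% and 31.5% of genes were at 0 in WT and 48.5% and 48.1% in the libraries labelled Ythdf1 KO, though these had more reads. The median log2 difference went from -0.97 at those means to 0.08 at means of 2000 or more.

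**Figure D3:**
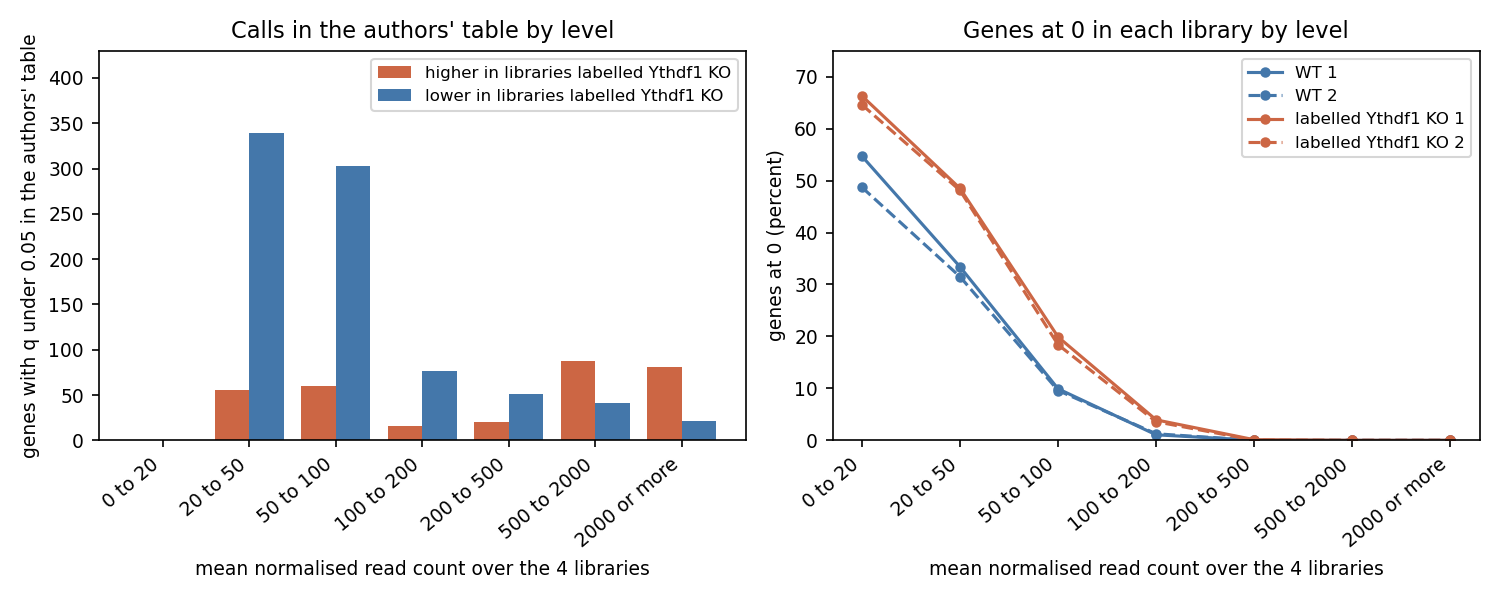
Left, genes with q under 0.05 in the authors' deposited table, higher and lower in the libraries labelled Ythdf1 KO, by mean normalised read count over the 4 libraries; right, percent of genes at 0 in each library in the same bins, with a line per library. At means from 20 to 50 there are 56 higher and 339 lower calls, and from 500 to 2000 there are 87 and 41.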

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

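The edgeR and DESeq2 fits, the fit to genes with a mean of at least 500, the estimated correlation in the alternative fits and the authors' values per gene were chosen after seeing the data. The count of 0 called genes stood under 19 alternatives and moved under 5: limma without a trend called 352 genes (59 higher, 293 lower), DESeq2 657 on summed reads (125 and 532) and 1110 on the most abundant transcript (342 and 768), and 3214 transcripts and 1152 genes had q under 0.05 in the authors' deposited table. Leaving out the trend gives every gene the same prior spread, so genes of high spread pass more easily; the cause of the other differences was not tested. Ythdf1 kept its direction under every alternative run, from 0.68 to 1.17 with a library left out, and passed only on the most abundant transcript in DESeq2 (0.918) and in the authors' values (0.906).

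Camera called 2 lists, 5 without a filter and with edgeR on summed reads, 1 on the most abundant transcript, 1 to 3 with a library left out, and 0 with quantile normalisation, with an estimated correlation (in this and in each other fit) or with fry. Quantile normalisation moved the median log2 difference of all genes from -0.09 to 0.03, and leaving out ribosomal RNA and the 20 most abundant genes moved it to -0.13. The interferon response list lost its call with quantile normalisation (median 0.303), on the most abundant transcript (0.267), at a mean of at least 500 (0.169), with an estimated correlation (adjusted p = 0.875) and with fry (0.868). Leaving out a library gave medians from 0.0288 to 0.394, with the call lost without WT 1 and without Ythdf1 KO 1. The ribosomal protein list lost its call with quantile normalisation (0.138), an estimated correlation (0.875) and fry (0.868), and its median ranged from 0.0787 to 0.294 with a library left out, the call being lost without WT 1 and without Ythdf1 KO 2. The cause was not tested.

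The values gave no sign that replicate numbers pair the samples. The replicate differences of both groups correlated at -0.0069 over 23252 genes and at 0.0225 over the abundant ones, which leaves a weak shared effect possible. With the replicate block, 0 genes were called, with 1610 at an unadjusted p under 0.05, 1 list was called, and the interferon response list had a median of 0.237 with an adjusted p = 0.0537.

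Medians of uncalled lists turned sign as follows, the cause not being tested. With quantile normalisation they became -0.0441 for stem cell and Wnt targets, 0.00402 for enteroendocrine, 0.0237 for tuft, -0.0246 for junction and 0.272 for stroma and muscle genes. Without ribosomal RNA and the 20 most abundant genes they became -0.0581 for stem cell and Wnt targets, -0.00161 for junction, -0.00654 for NF-kB and cytokine and -0.035 for small intestine genes. The stem cell list reached -0.00985 on the most abundant transcript, and small intestine genes -0.23 without a filter and -0.145 at a mean of at least 500. Fatty acid oxidation genes reached 0.0215 and 0.0149 in edgeR on the most abundant transcript (TMM and RLE) and 0.00726 at a mean of at least 500. Lymphocyte genes reached 0.0156 in edgeR on summed reads and 0.0202 and 0.0133 on the most abundant transcript.

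In edgeR on summed reads, medians that kept their sign but moved most were -0.447 for myeloid, -0.374 for MHC class II, -0.469 for stroma, 0.607 for antimicrobial and 0.0342 for erythroid genes.

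With a library left out, medians ranged from -0.196 to 0.192 for stem cell and Wnt targets, -0.0262 to 0.292 for goblet, -0.517 to 0.236 for enteroendocrine, -0.41 to 0.474 for tuft, -0.0578 to 0.0809 for junction, -0.174 to 0.938 for antimicrobial, -0.106 to 0.235 for NF-kB and -0.299 to 0.135 for ferroptosis genes. They ranged from -0.218 to 0.171 for fatty acid oxidation, -0.275 to 0.0902 for cholesterol, -0.116 to 0.291 for clock, -0.261 to 0.102 for small intestine, -0.929 to 0.704 for lymphocyte, -0.94 to 0.301 for stroma and -0.605 to 2.58 for erythroid genes. The other uncalled lists kept their sign, with ranges of 0.0324 to 0.15 for m6A machinery, 0.104 to 0.388 for proliferation, -0.177 to -0.102 for absorptive, -0.891 to -0.303 for MHC class II, 0.142 to 0.211 for unfolded protein response, 0.0278 to 0.415 for immediate early, 0.0679 to 0.172 for p53, -0.727 to -0.0973 for xenobiotic, 0.0681 to 0.259 for translation factor, 0.33 to 1.87 for Hox, -1.97 to -0.299 for myeloid, -0.806 to -0.488 for endothelium and nerve and 0.323 to 0.626 for sex-linked genes. Of the named genes, Ythdf2 ranged from -0.0205 to 1.09 and Ccl25 from -2.37 to 0.849. With 1 library left in a group, that library is assumed to vary like the others. The file holds a single unit, so the alternative of another unit was not run, and DESeq2 gave no camera test. Genes under a mean of 200 varied most within the groups, and 22.5% to 34.9% of them were at 0 in a library.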

Other observations

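The tests of sequencing depth, of isoforms, of the spread and the labels behind Ythdf1, of the histone and stress genes, of receptor genes against genes of their level, of the ribosomal list per pair of libraries against matched lists, and of DESeq2 calls across splits were chosen after the results were seen. Histone genes are a group found in the data and not among the fixed lists, so their test runs on the values that drew attention to them. Over 61 histone genes the median log2 difference was 0.30, at percentile 100 of 10000 lists matched on level, with 21 genes above both WT libraries and 5 below. Hist1h3e stood at 2873 and 2171 in WT and at 4357 and 4551 in the libraries labelled Ythdf1 KO, and Hist1h2be at 2337 and 2661 against 3716 and 5359. Camera gave them an adjusted p = 0.00555 over the 5 lists examined this way. With an estimated correlation, a test of little power here, the adjusted p was 0.336. Histone genes vary together, so random lists understate the spread of their median, and the differences were larger against Ythdf1 KO 2 (0.53 and 0.47) than against Ythdf1 KO 1 (0.19 and 0.13). A joint shift of these genes with the label cannot be told apart from variation between single libraries, since the largest difference within a group was 0.48.

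A hypothesis on amino acid stress stays open. Gdf15, a stress-induced secreted factor, stood at 1029 and 813.7 in WT and at 2222 and 1984 in the libraries labelled Ythdf1 KO, and Nars, the asparaginyl-tRNA synthetase, at 3102 and 3602 against 6189 and 6007. Over 17 targets of the integrated stress response the median was 0.07, at percentile 71.5 of lists matched on level. A wider list of 28 targets, also written after gene values were seen, lay at percentile 98.4, with a smallest difference between a library labelled Ythdf1 KO and a WT library of 0.22 and at most 0.07 within a group. For that wider list camera gave an adjusted p = 0.0128 and fry 0.0249. With an estimated correlation, a test of little power here, camera gave an adjusted p = 0.336. Without the 5 members that the authors called, all of them higher, the wider list lay at percentile 66.6 (camera adjusted p = 0.164, fry 0.275), a fall that leaving out higher genes brings in part by itself, and the passes depend on these members. Asns, a classical target, stood at 594 and 1452 in WT and at 751.4 and 556.7 in the others.

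For the lower calls among genes of low level, depth argues against a lack of reads, since the shallowest library labelled Ythdf1 KO held 1.06 times the reads of the deepest WT library, and isoforms counted repeatedly are argued against by a lower share of 72.2% with 1 transcript per gene. Fewer distinct molecules in the libraries labelled Ythdf1 KO would leave summed values alone, but genes under a mean of 200 had a ratio of sums, relative to the other genes, of 0.698. Olfactory, vomeronasal and taste receptor genes, which colon hardly uses, had a ratio of 0.568 over 350 genes, with both libraries labelled Ythdf1 KO (8525 and 7288) below both WT libraries (14660 and 13190). Most of these genes are themselves of low level, but lists of other genes matched on level had a ratio of 0.714 (0.617 to 0.829), so the receptor genes lay lower than their level alone gives. A larger background in the WT libraries, such as unspliced RNA or genomic DNA, is a candidate explanation, and a biological loss of low-level RNAs with genotype stays open.

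Ythdf1 lay higher in the libraries labelled Ythdf1 KO. Its log2 difference was at percentile 98.4, in size, of the 500 genes nearest in level. Ythdf1 has 1 listed transcript, so its values are the same in both limma-trend fits, and only the spread borrowed from other genes differs. The SE was 0.368 on summed transcripts, with no unadjusted p under 0.05, and 0.278 on the most abundant transcripts, with one under 0.05. Neither adjusted p passed (0.732 and 0.759). Whether the difference exceeds the spread between 2 libraries per group thus depends on the fit and cannot be told. The 66 tested genes within 1 Mb had a median of -0.13, at percentile 21.2 of lists matched on level, which argues against a shift of the neighbourhood. Exchanged labels, which a ratio of 1.87 would also give, cannot be told apart from transcripts that persist in a knockout, since no value here shows the genotype.

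The ribosomal protein list lay at percentile 99.8 of lists matched on level and at 98.9 of lists matched on level and gene span, but such genes vary together, so random lists understate the spread of their median. Uncalled lists were as extreme when matched on level: Hox at 99.9, proliferation at 99.7 and immediate early at 99.5, with xenobiotic at 0.08 and absorptive at 0.9. The percentile therefore does not single out the ribosomal protein list. Against lists matched on level, the ribosomal protein list lay 0.23 and 0.17 higher in Ythdf1 KO 2 than in the WT libraries, 0.04 and -0.03 in Ythdf1 KO 1, and 0.16 higher in Ythdf1 KO 2 than in Ythdf1 KO 1. A general shift with level or span therefore cannot be told apart from a shift of the list, since the excess is within the spread of a group. The median difference was above 0 in 4 of 4 pairs of a library labelled Ythdf1 KO and a WT library, but was 0.0063 for Ythdf1 KO 1 against WT 2, and the libraries labelled Ythdf1 KO differed from each other by 0.19. Whether 1 library of a group decides the call cannot be told apart from a difference of the groups with 2 libraries each, and a biological difference of genotype stays untested.

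Splits of the 4 libraries into 2 and 2 number 3, too few for a share under 0.05. DESeq2 on the most abundant transcript called 1110 genes in the labelled split and at most 466 in the others, so 1 of 3 splits gave as many. limma-trend gave 1529 genes at an unadjusted p under 0.05 in the labelled split and at most 845 in the others, again 1 of 3.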
